A study of Bos taurus with 15 samples.

How the data were processed

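Total RNA of bovine oocytes and of embryos from the 1-cell stage to the blastocyst was amplified in 3 rounds, labelled with biotin and hybridized to Affymetrix Bovine Genome arrays, per the labels' protocols. The authors deposited 1 table with an intensity on a linear scale for each of 24128 probe sets on 15 arrays. The method that summarised probes into probe sets, the scaling between arrays, any floor and the software are not given in the sources used here. Values ran from 0.39 to 20788, and 2.56% of them were exactly 1.00, although 1.00 was not the lowest value. No detection call was used here, so a low signal has no stated limit of background. Scaled arrays show each transcript's share of the amplified RNA, not its amount per embryo.

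Array medians of replicates differed by at most 0.34 on the log2 scale, so the deposited values were used without further normalization. After 112 control probe sets were left out, 24016 probe sets were tested on log2(value + 16), and every fold change is on that scale, which understates changes of low signals. Groups and replicate numbers came from the titles in the labels. For names, the platform's annotation was updated through gene identifiers to the RefSeq table of assembly ARS-UCD2.0. Of the tested probe sets, 13292 had 1 gene symbol, 86 had several and were left unnamed, and 10638 had none, and 13263 had an identifier in the RefSeq table. They named 9155 genes. No genome was used here, so no coordinates are given. No probe set named ZAR1, NANOG, CDX2, GATA3 or NPM1, which were to be given in any case.

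The test was limma (version 3.58.1, R 4.3.3): a mean per stage fitted to all 15 arrays, with an empirical Bayes variance that followed the mean intensity, and Benjamini-Hochberg adjustment over all probe sets at 0.05. The 7 residual degrees of freedom came from the 4 replicated stages, and the single arrays added none. The p-values measure the spread between these arrays. For each gene the probe set with the highest mean was used. Lists of 1078 genes in 21 groups, of which 808 were measured, were fixed before the data were examined and tested with camera at a preset correlation of 0.01, with the adjustment made over the lists, and again with the correlation estimated per list.

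Named genes followed a rule written before the data were examined. It took, per replicated comparison, the 8 largest rises and 8 largest falls past the test whose arrays did not overlap and whose higher mean lay above the median, up to 4 members of each list past the test or else its 2 highest members, the 6 largest lasting rises and falls of at least 4-fold per step between single arrays, and a fixed set of marker genes. Non-overlap of 3 against 3 arrays happens by chance for 10% of genes, and of 2 against 3, as in the 1-cell comparison, for a larger share. Fewer genes met the rule among the falls of the 1-cell and blastocyst comparisons. Positions between oocyte and morula were medians over probe sets past the test by at least 2-fold, with oocyte and morula arrays left out of their own reference.

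The procedure was tested on simulated data with the oocyte means at every stage, the real spreads and 200 changed probe sets among 24016. The real morula comparison called far more, 4550, so the recovery given for it here may be too low. At a log2 change of 2, 38% of 1-cell, 50% of morula and 44% of blastocyst changes were recovered, and at a log2 change of 4, 88%, 90% and 90%. The simulation gave 4, 10 and 3 false calls. It drew independent errors, without the structure seen among the arrays.

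Same-numbered arrays deviated together from their stage means, with correlations of 0.142, 0.107 and 0.182 between oocytes and morulae and 0.195, 0.106 and 0.306 between morulae and blastocysts. Between oocytes and 1-cell embryos they were 0.183 and -0.115. An alternative fit with the replicate number as a block, fixed beforehand, took in all replicated stages, the 1-cell arrays included. By these correlations it was read as a paired fit for oocytes, morulae and blastocysts alone. But oocyte 3 and 1-cell 2, of different numbers, correlated at 0.192, and 1-cell 2 and morula 3 at 0.175. Deviations within a stage are also tied together by their mean. The correlations thus do not tell pairing by number from another shared deviation. Alternatives fixed before the data were examined were quantile normalization, median centring, a filter on low probe sets, pseudocounts of 1 and 64, other variance models, the arrays of the compared stages alone, a replicate block and leaving out each replicate. Alternatives chosen after seeing the data were the spike-in class as a block, each class alone, and leaving out the arrays numbered 3. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.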

Results

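Transcript levels were measured in bovine (Bos taurus) oocytes and in embryos produced in vitro, from the 1-cell stage to the blastocyst, the stage at which the embryo has formed a fluid-filled cavity and its first epithelium. Each of 15 Affymetrix Bovine Genome arrays gave 1 signal, an intensity on a linear scale, for 24128 probe sets. Oocytes, morulae and blastocysts had 3 arrays each and 1-cell embryos had 2, while 2-cell, 4-cell, 8-cell and 16-cell embryos had 1 array each. The labels call the replicates biological. The stages cover the interval in which the embryo passes from transcripts stored in the oocyte to transcripts of its own genome, and the series followed expression through it. Mean signal per array ran from 553 to 713 and median signal from 39.7 to 62.1. The number of arrays limited the precision, and stages with 1 array had no replicate check.

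The replicates were not equally close. Morula arrays 1 and 2 differed by at least 4-fold at 47 probe sets and oocyte arrays 1 and 2 at 320, whereas the arrays numbered 3 of the oocyte, morula and blastocyst stages differed from the other arrays of their stage at 1979 to 3065. Transcripts of bacterial origin that are added to RNA as labelling controls (poly(A) spike-in transcripts) gave signal on 9 arrays and were near background on 6. The 9 were oocyte 2 and 3, 1-cell 2, morula 3, blastocyst 3 and all 4 single arrays. Oocyte 2 carried a different mix, with thr at 2632 and lys at 2815, against thr of 124 to 290 and lys of 8476 to 14811 on the other 8. The ratio of middle to 3' signal of GAPDH, a sign of how complete the labelled RNA was, was 0.0977, 0.237 and 0.0374 on the oocyte arrays, 0.625, 0.367 and 0.100 on the morula arrays and 0.544, 0.643 and 0.339 on the blastocyst arrays. The ratio of the cyclophilin control was 0.0607, 0.103 and 0.0141 on the oocyte arrays, 0.273, 0.322 and 0.179 on the morula arrays and 0.766, 0.499 and 0.525 on the blastocyst arrays, lower on each oocyte array than on any of the other 6. That of the eIF-4E control went another way: it was highest on array 3 of these stages (0.235, 0.888 and 0.163), and arrays 1 and 2 had 0.0388 and 0.0964 in oocytes against 0.0636 and 0.0842 in morulae. The cyclophilin ratio was also lower on each morula array than on any blastocyst array, while the ranges of GAPDH and eIF-4E overlapped between those stages. These values stand beside every comparison of stages below.

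Between the oocyte and the morula, transcripts stored by the oocyte fell as a list and lists of protein synthesis and energy metabolism were higher. With the correlation estimated per list, only the fall of the maternal list passed. ZP2, which encodes a protein of the egg coat, had a signal of 11933 ± 772 (SD, n = 3) in oocytes and 92.9 ± 57.1 (SD, n = 3) in morulae, a log2 change of -6.94 (SE 0.49, adjusted p = 2.63e-05). KRT18, a keratin of simple epithelia, went from 22.2 ± 16.6 to 2906 ± 1844 (SD, n = 3 each), a log2 change of 6.19 (SE 0.53, adjusted p = 6.27e-05). NDUFB10, a subunit of respiratory complex I, rose by 6.34 (SE 0.54, adjusted p = 6.46e-05), and the ribosomal protein gene RPL3 rose by 5.19 (SE 0.74, adjusted p = 9.69e-04), with a second probe set at 1.07 that did not pass. Of 24016 probe sets tested, 4550 passed, 2830 higher and 1720 lower in the morula, and at 1 probe set per gene 1619 genes were higher and 790 lower among 9155. Quantile normalization gave 2432 higher and 2301 lower and centring each array on its median gave 2511 and 2269, with the median change of all probe sets moving from 0.04 to -0.06 and -0.14, so the excess of rises depended on the scaling. Without the arrays numbered 3, an alternative chosen after seeing the data, 7102 probe sets passed.

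Maternal transcripts made up the most uniform fall. Of 17 measured genes of the list of oocyte and maternal-effect genes, 11 fell, none rose and 6 did not pass, and 13 fell when adjusted over the list alone, with 2 higher (camera adjusted p = 2.77e-07, and adjusted p = 0.0217 with an estimated correlation). KPNA7, a nuclear import receptor of oocytes, fell by 7.30 on the log2 scale (SE 0.39), from 9216 ± 4315 to 39.0 ± 7.97 (SD, n = 3 each). MOS, the kinase that holds the mature oocyte in meiosis, fell by 6.25 (SE 0.64), and UCHL1 fell by 5.66 (SE 1.15). GDF9, an oocyte growth factor, fell by 4.21 (SE 0.44, adjusted p = 1.80e-04). BMP15 fell by 2.74 (SE 0.75, adjusted p = 0.0285) from oocyte signals that spread widely, 1970 ± 2437 (SD, n = 3), and ZP3 fell by 2.63 (SE 0.70, adjusted p = 0.0263). BMP15 did not pass without morula 1, 2 or 3 (adjusted p = 0.0895, 0.0691 and 0.0537), nor ZP3 without oocyte 2 or morula 1, 2 or 3 (adjusted p = 0.0666, 0.0713, 0.0638 and 0.0621), and neither passed with only the compared stages in the fit (adjusted p = 0.0963 and 0.0889). A second probe set of BMP15 did not pass (-0.79). Beside KPNA7 and ZP2, the largest falls of all named genes were those of LOC513055 at -7.86, RGS16 at -7.79, PLEKHG1 at -7.70, ARMC2 at -7.46, TECTB at -7.28 and ALG13 at -6.97, with adjusted p from 4.14e-06 to 7.43e-05. A second probe set of ARMC2 did not pass (-2.37).

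Most genes of the cytoplasmic ribosome rose, and so did fewer genes of its assembly. Of 63 measured ribosomal protein genes 45 rose and none fell (53 and 2 adjusted over the list alone), with a median log2 change of 2.09. RPL13 rose by 4.03 (SE 0.47), RPL7 by 3.97 (SE 0.31) and RPL10A by 3.84 (SE 0.55). The list passed with camera (adjusted p = 6.17e-12) but not with an estimated correlation (adjusted p = 0.226). Of 61 nucleolar and ribosome biogenesis genes 19 rose and 2 fell (23 and 2 adjusted over the list alone; camera adjusted p = 0.0130, and adjusted p = 0.460 with an estimated correlation). POLR1C, a subunit of RNA polymerases I and III, rose by 7.11 (SE 0.78), EMG1 by 5.35 (SE 0.46) and NOP16 by 4.95 (SE 0.62). Of 41 translation initiation and elongation factors 20 rose and 1 fell (23 and 1 adjusted over the list alone; camera adjusted p = 3.13e-05, and adjusted p = 0.226 with an estimated correlation). EIF3A rose by 6.30 (SE 0.59), EIF3G by 5.38 (SE 0.54) and EIF3D by 5.28 (SE 0.48), all subunits of the factor that recruits messenger RNA to the small ribosomal subunit, while EIF1AX rose by 1.35 (SE 0.35, adjusted p = 0.0223). A second probe set of EIF3A, at -0.03, did not pass. EIF1AX did not pass without oocyte 1 or 2 or morula 1 or 2 (adjusted p = 0.0621, 0.0730, 0.0677 and 0.0733), with each array centred on its median (adjusted p = 0.0672) or with only the compared stages in the fit (adjusted p = 0.0604).

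Most genes of oxidative phosphorylation rose as well. Of 74 nuclear-encoded oxidative phosphorylation genes 53 rose, none fell and 21 did not pass (61 and 0 adjusted over the list alone), with a median log2 change of 2.38. UQCR10 of complex III rose by 5.75 (SE 0.44), NDUFS8 of complex I by 5.22 (SE 0.55) and SDHB of complex II by 5.22 (SE 0.86). The list had a camera adjusted p of 8.64e-15, and adjusted p = 0.141 with an estimated correlation. Of 31 genes of glucose transport and glycolysis 17 rose and 1 fell (19 and 2 adjusted over the list alone; camera adjusted p = 7.20e-04, and adjusted p = 0.226 with an estimated correlation). The pyruvate dehydrogenase genes PDHA1 and PDHB rose by 5.23 (SE 0.40) and 4.91 (SE 0.32), although the other 3 probe sets of PDHA1 did not pass and 1 of the other 2 of PDHB passed in the opposite direction (-1.44). GAPDH rose by 4.11 (SE 0.92, adjusted p = 0.0111) at a probe set whose signals ran with those of the middle control. The 3' control of GAPDH differed less between the stages, at 522, 1297 and 4690.0 on the oocyte and 11447, 10949.7 and 6708 on the morula arrays. ALDH5A1, which encodes succinate semialdehyde dehydrogenase, rose by 7.58, GK, which encodes glycerol kinase, by 7.19, ACSS1, a mitochondrial acetyl-CoA synthetase, by 7.03, and AGPAT4, an enzyme of phospholipid synthesis, by 7.67, among the largest rises of all named genes, with adjusted p from 1.09e-05 to 3.56e-05. CD99, AARS1 and ALPI rose by 7.11, 6.97 and 6.84, with a second probe set of ALPI, at 0.11, that did not pass.

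Some genes of RNA processing and protein turnover rose. Of 64 spliceosome and pre-mRNA processing genes 21 rose and none fell (27 and 0 adjusted over the list alone; camera adjusted p = 2.04e-04, and adjusted p = 0.141 with an estimated correlation). DDX39A rose by 5.80 (SE 0.43), PRPF31 by 4.98 (SE 0.91) and SNRNP70 by 4.13 (SE 0.49), although a second probe set of PRPF31, at -1.81, did not pass. Of 37 proteasome subunits 17 rose and 2 fell (20 and 2 adjusted over the list alone; camera adjusted p = 0.00102, and adjusted p = 0.249 with an estimated correlation), with PSMA1 up by 5.34 (SE 0.73) and PSME1 by 5.00 (SE 0.71).

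Some genes of the first embryonic epithelium were higher in morulae. Of 34 epithelial junction and blastocoel transport genes 11 rose and 1 fell (13 and 2 adjusted over the list alone), and the list passed with camera (adjusted p = 0.0405) but not with an estimated correlation (adjusted p = 0.283) or without the lowest 33% of probe sets by mean (adjusted p = 0.0803). It also did not pass without oocyte 3 (adjusted p = 0.166), without morula 1 (adjusted p = 0.0855), with the mean of all probe sets per gene (adjusted p = 0.0676) or with a pseudocount of 64 (adjusted p = 0.0573). GJB5, a gap junction protein, rose by 6.49 (SE 0.55), the tight junction genes CLDN4 and CLDN6 by 6.15 (SE 0.48) and 6.02 (SE 0.50), and ATP1B3, a subunit of the sodium pump, by 4.16 (SE 0.51). Second probe sets of CLDN6 (0.41) and ATP1B3 (0.38) did not pass. Of 31 trophectoderm genes 8 rose and none fell (8 and 1 adjusted over the list alone), without the list passing (camera adjusted p = 0.141), except without the lowest 33% of probe sets by mean (adjusted p = 0.0193). TEAD4, a transcription factor of the trophectoderm, rose by 5.16 (SE 0.57), DAB2 by 6.38 (SE 0.45) and KRT7 by 4.05 (SE 0.40). Of 13 pluripotency and inner cell mass genes 5 rose and none fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.168), among them KLF4 by 2.67 (SE 0.45) and POU5F1 by 1.25 (SE 0.33, adjusted p = 0.0245). POU5F1 did not pass when each array was centred on its median (adjusted p = 0.0698) or without oocyte 1, oocyte 2, morula 1 or morula 2 (adjusted p = 0.0867, 0.0772, 0.0672 and 0.0784) or with only the compared stages in the fit (adjusted p = 0.0520). Among 26 hypoblast and extracellular matrix genes 8 rose and 2 fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.472), with GATA6, a transcription factor of the hypoblast, up by 5.16 (SE 0.58) and FN1 by 4.80 (SE 0.52), with a second probe set of FN1 at 0.36 that did not pass.

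Chromatin and cell cycle genes went both ways. Of 43 DNA and chromatin modifiers 10 rose and 3 fell (10 and 5 adjusted over the list alone; camera adjusted p = 0.697). The de novo DNA methyltransferase DNMT3A rose by 5.53 (SE 0.59), from 24.6 ± 17.1 to 2025 ± 1090 (SD, n = 3 each), whereas the maintenance methyltransferase DNMT1 fell by 3.11 (SE 0.49) and its partner UHRF1 fell by 4.57 (SE 0.76), from 10180.0 ± 1611 to 459 ± 239.8 (SD, n = 3 each). The other 2 probe sets of DNMT3A did not pass. DNMT3B had a change of -1.81 (SE 0.82, adjusted p = 0.165) and did not pass. Of 55 mitotic and meiotic cell cycle genes 8 rose and 7 fell (9 and 7 adjusted over the list alone; camera adjusted p = 0.885), with CCND2 up by 4.99 (SE 0.88) and CDK4 by 3.81 (SE 0.55). Of 53 heat shock, redox and stress genes 16 rose and 3 fell (18 and 4 adjusted over the list alone; camera adjusted p = 0.168), with BAK1 up by 6.38 (SE 0.77), and of 26 cholesterol and fatty acid synthesis genes 7 rose and 2 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.802), with ELOVL6 up by 6.17 (SE 0.41) and INSIG1 down at -4.87 (SE 1.09). Of 36 genes of mRNA deadenylation, decay and poly(A) binding 6 rose and 3 fell (6 and 4 adjusted over the list alone; camera adjusted p = 0.782), and of 45 transcription initiation genes 7 rose and 3 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.927). HSPA1A and ACTB did not pass, with changes of -1.47 (SE 1.15) and 0.79 (SE 0.34).

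Markers of other cell types did not shift as lists. Of 35 cumulus and granulosa cell markers 3 rose and 4 fell (3 and 6 adjusted over the list alone; camera adjusted p = 0.472). STAR, TNFAIP6 and VCAN were lower, with changes of -3.68 (SE 0.78), -3.45 (SE 0.90) and -2.80 (SE 0.47), the last with 2 of 3 probe sets past the test. TNFAIP6 did not pass without oocyte 1 or 3 or morula 1, 2 or 3 (adjusted p = 0.0813, 0.0644, 0.0681, 0.0521 and 0.0631) or with only the compared stages in the fit (adjusted p = 0.0540), and a second probe set of it, at 0.22, did not pass. HAS2, which makes hyaluronan, had 3 probe sets past the test in opposite directions, from -6.20 to 3.83, with 2.53 at the one used. Of 11 sperm and spermatid markers 1 rose (1 adjusted over the list alone; camera adjusted p = 0.885), ODF2 by 3.58 (SE 0.42), and of 18 blood and immune cell markers 1 rose (1 adjusted over the list alone; camera adjusted p = 0.885), HBB by 4.36 (SE 0.81) at a morula signal of 1017 ± 680.2 (SD, n = 3), with 2 of its 4 probe sets past the test.

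**Figure D1:**
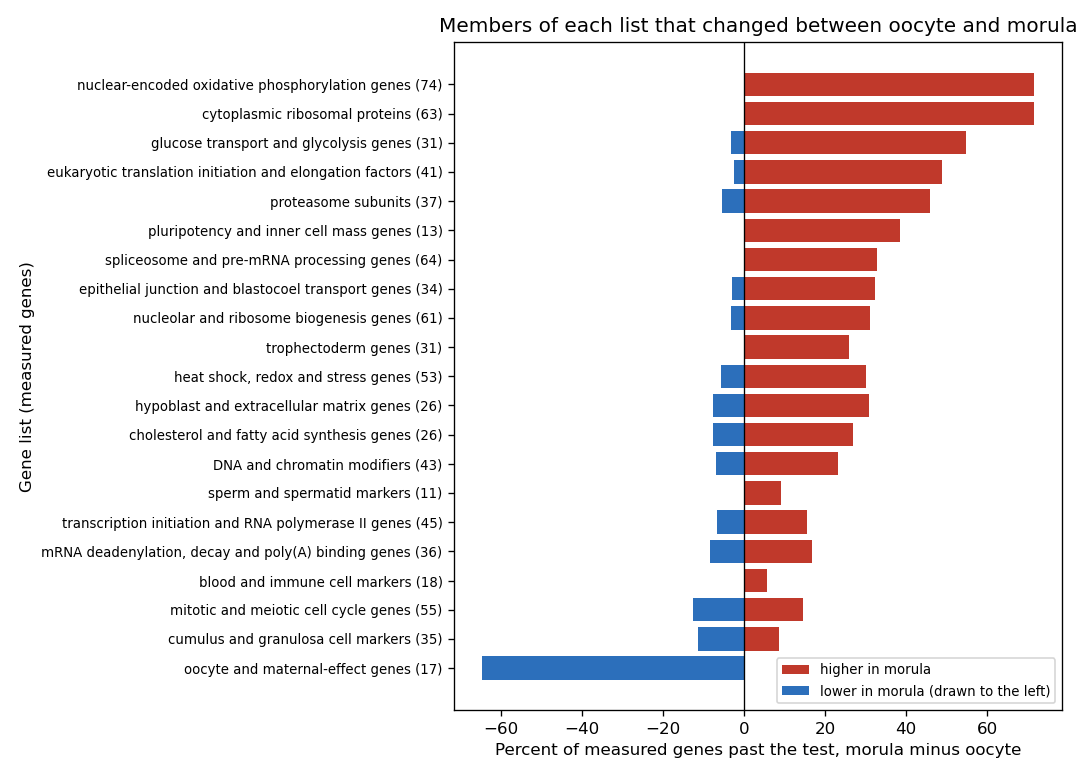
Percent of the measured genes of each list that passed the test between oocyte and morula, with genes higher in the morula drawn to the right in red and genes lower drawn to the left in blue; the number of measured genes stands beside each list name. All 53 oxidative phosphorylation genes past the test were higher in the morula and all 11 maternal genes past the test were lower.

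The single arrays of the cleavage stages were placed between oocyte and morula to ask when these changes appeared. A position of 0 is the oocyte mean and 1 the morula mean, taken as the median over probe sets that rose (2726) or fell (1619) by at least 2-fold. For rising probe sets the 2-cell array lay at 0.00898, the 4-cell array at 0.0349 and the 8-cell array at 0.0463, all within the range of the left-out oocyte arrays or next to it (-0.0575 to 0.0427), and the 16-cell array lay at 0.820. For falling probe sets the positions were 0.0995, 0.0911, 0.222 and 0.617, against -0.0385 to 0.0486 for left-out oocyte arrays. Blastocyst arrays lay at 0.892 to 0.929 for rising and 0.902 to 0.995 for falling probe sets. The probe sets were chosen on the oocyte and morula arrays themselves, so the range of the left-out arrays is narrower than that of independent arrays would be.

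**Figure D2:**
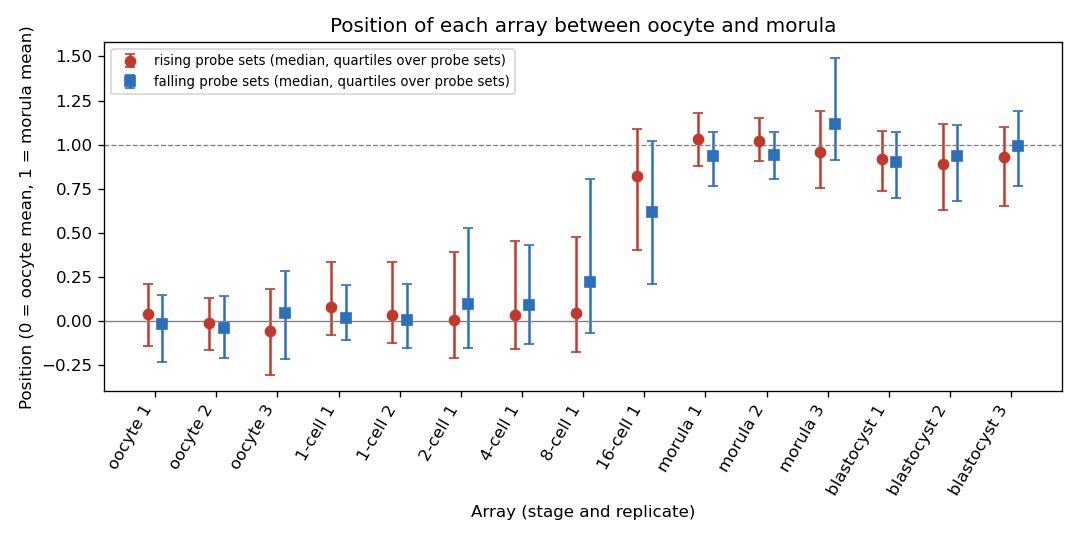
Position of each of the 15 arrays between the oocyte mean (0) and the morula mean (1), as the median over rising (red circles) or falling (blue squares) probe sets, with bars from the lower to the upper quartile over probe sets, which are not replicates. The 8-cell array sits at 0.0463 for rising probe sets and the 16-cell array at 0.820.

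Genes differed in when they left the oocyte level. GDF9 had a signal of 2090 in the 2-cell, 1863 in the 4-cell and 1122 in the 8-cell array and 56.2 in the 16-cell array, while UHRF1 was still at 8261 in the 16-cell array. RPL3 went from 27.8 in the 8-cell to 2318 in the 16-cell array, and EIF1AX from 2190 to 8117. KRT18 and GJB5 were at 8.75 and 28.8 in the 16-cell array, within or under the range of the oocyte arrays, while GJB5 had been at 410 in the 4-cell and 176 in the 8-cell array, above every oocyte array. That array also carried some transcripts of stromal and granulosa cells far above the 8-cell array and the morula mean, with VIM at 1959, COL1A2 at 2432, LUM at 1397 and FST at 945, whereas COL1A1 was at 8.43 and COL3A1 at 25.9. These 6 genes were chosen after their values were seen.

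**Figure D3:**
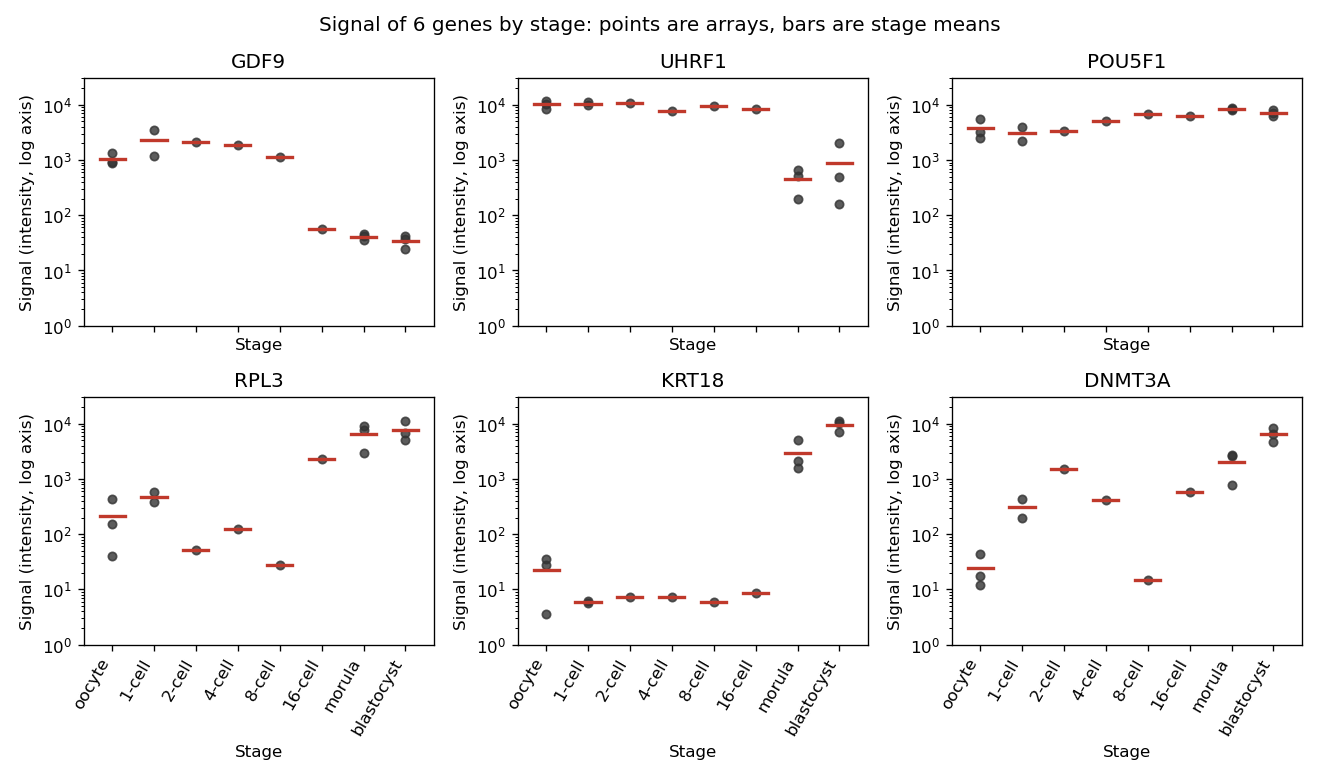
Signal (intensity, log axis) of GDF9, UHRF1, POU5F1, RPL3, KRT18 and DNMT3A by stage, with a point for each array and a bar at the stage mean. GDF9 is at 1122 in the 8-cell and 56.2 in the 16-cell array, while KRT18 is at 8.75 in the 16-cell array and at a mean of 2906 in morulae.

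Between consecutive single arrays, 4667 probe sets differed by at least 4-fold from the 8-cell to the 16-cell array, 3281 higher and 1386 lower. The ratios of middle to 3' signal also differed between the 8-cell and the 16-cell array. They were 0.01155 and 0.4747 for cyclophilin, 0.05715 and 0.1342 for GAPDH and, the other way, 0.2326 and 0.08525 for eIF-4E. Replicates of one stage differed at 47 to 3065 probe sets, with a median of 2163. Pairs parted by the spike-in mix that 8 arrays share differed at 987 to 3065, and the other pairs at 47 to 352. The single arrays all carried that mix and no replicate pair shared it, so no like-for-like yardstick exists for the steps between them. The steps from 2-cell to 4-cell (2356) and from 4-cell to 8-cell (2891) lay within the full range of replicate pairs. So did the medians from oocyte to 1-cell (1895.5), from 1-cell to 2-cell (2551.5) and from morula to blastocyst (1936), and the step from 16-cell to morula had a median of 3456. Genes that moved by at least 4-fold and kept at least 50% of the move in every later array numbered 823 upward and 245 downward at the 8-cell to 16-cell step, 136 and 148 at the 4-cell to 8-cell step and 133 and 80 at the 2-cell to 4-cell step. An earlier step has to hold in more later arrays, the 16-cell array included, so its counts are lowered by construction and the 3 steps are not on a par. From 8-cell to 16-cell, EWSR1, an RNA-binding protein, went from 5.08 to 8778, the small GTPase RND3 from 9.92 to 6599 and the proteasome gene PSMB6 from 18.0 to 6763, while SLC5A1, a sodium and glucose transporter, went from 6158 to 24.1. The 8-cell values of these 3 rising genes lay under their oocyte means of 146, 215 and 509.7, and PSMB6 was at 866 in the 4-cell array. Of the 6 largest falls of this step, only SLC5A1 started near its oocyte mean, which was 5313. The rest fell from 8-cell signals above their oocyte means. These were RFX5 at 7103 against 946, ZNF362 at 3400 against 677, SIL1 at 1300 against 53.0, SIX3 at 4362 against 292 and ARHGAP10 at 1324 against 8.28. From 4-cell to 8-cell, the splicing factor SFPQ went from 1 to 1134, EIF3A from 9.79 to 1540, KCTD20 from 44.3 to 5407 and PNRC1 from 34.6 to 5329. From 2-cell to 4-cell, EEF1B2 went from 14.6 to 3052, its 2-cell value far below the oocyte mean of 2719. TKT went from 14.2 to 1218, against 43.5, 11.9 and 3382 on the oocyte arrays. The steps between single arrays were compared by size and not tested.

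Between the oocyte and the 1-cell embryo, few probe sets changed, and more rose than fell. BRD8, a bromodomain protein of a histone acetyltransferase complex, had signals of 276 ± 168 (SD, n = 3) in oocytes and 3837 ± 696 (SD, n = 2) in 1-cell embryos, a log2 change of 3.89 (SE 0.47, adjusted p = 0.0164). EXOSC6, a subunit of the RNA exosome, rose by 4.00 (SE 0.40, adjusted p = 0.00945), and the interferon-induced gene MX1 fell by 3.60 (SE 0.30, adjusted p = 0.00707), from 272 ± 56.5 (SD, n = 3) to 7.62 ± 4.05 (SD, n = 2). GEM, a small GTPase, fell by 4.91 (SE 0.59, adjusted p = 0.0164). In the 16-cell array MX1 was at 1399 and GEM at 3296, against at most 48.3 and 21.2 on the other arrays of embryos. The source of these signals was not tested. In all, 65 probe sets passed, 56 higher and 9 lower, with 1824 at an unadjusted p under 0.05.

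The other rises past the test included TIMM9, of the mitochondrial import machinery, at 4.34 (SE 0.67), GLRX3 at 4.02 (SE 0.62), NUDC at 3.97 (SE 0.59), TGOLN2 at 3.95 (SE 0.58), the nucleolar gene RRP1 at 3.83 (SE 0.59) and PHLDA2 at 3.59 (SE 0.58), with adjusted p from 0.0368 to 0.0449. CNOT1, the scaffold of the CCR4-NOT deadenylase, rose by 2.10 (SE 0.32, adjusted p = 0.0379) and HSPA4 by 2.22 (SE 0.36, adjusted p = 0.0449). GAL fell by 3.10 (SE 0.43) and RACK1 fell by 3.00 (SE 0.42). A second probe set of BRD8, GLRX3, EXOSC6, TGOLN2, HSPA4 and RACK1 did not pass. None of 17 oocyte and maternal-effect genes passed, and GDF9 had a change of 0.97 (SE 0.49, adjusted p = 0.745). Nucleolar and ribosome biogenesis genes were higher as a list (1 of 61 rose, 5 adjusted over the list alone; camera adjusted p = 0.00166), and ribosomal proteins (0 of 63 passed, 2 lower adjusted over the list alone; camera adjusted p = 1.55e-05) and hypoblast and extracellular matrix genes (0 of 26 passed, 1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00289) were lower. None of the 3 lists passed with an estimated correlation (adjusted p = 0.555 for each). The nucleolar list did not pass without oocyte 1 or oocyte 2 (adjusted p = 0.0751 and 0.0769), and the ribosomal list without oocyte 3 or 1-cell 1 (adjusted p = 0.0515 and 0.714). The cumulus, sperm and blood marker lists did not pass (camera adjusted p = 0.113, 0.785 and 0.579).

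The 1-cell calls were not robust. With only the oocyte and 1-cell arrays in the fit, limma called 0 probe sets (1606 at an unadjusted p under 0.05). The count was 11, 32 and 135 without oocyte 1, 2 and 3, 169 and 8 without 1-cell 1 and 2, 9 and 12 without morula 1 and 2, and 17, 25 and 20 without blastocyst 1, 2 and 3, and it was 419 without the arrays numbered 3.

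Between the morula and the blastocyst, genes of the trophectoderm, the outer epithelium that gives rise to the placenta, and of cholesterol and fatty acid synthesis were higher as lists. HSD3B1, an enzyme of steroid hormone synthesis, had signals of 35.4 ± 10.8 in morulae and 2491 ± 1240.3 in blastocysts (SD, n = 3 each), a log2 change of 5.51 (SE 0.42, adjusted p = 0.00352). EPAS1, a hypoxia-inducible transcription factor, rose by 5.64 (SE 0.49, adjusted p = 0.00476). IFNT2, an interferon tau secreted by the ruminant trophectoderm, rose by 3.71 (SE 0.52, adjusted p = 0.0327), from 51.3 ± 36.1 to 877 ± 577 (SD, n = 3 each). ACAT2, of the first step of cholesterol synthesis, rose by 2.50 (SE 0.39, adjusted p = 0.0487). IFNT2 lost its call in 10 settings fixed beforehand and ACAT2 in 14. EPAS1 and ACAT2 rose from a low in the morula. EPAS1 had been at 2407 to 2970 on the oocyte arrays, and ACAT2 at 1495 to 3517 on the 1-cell to 4-cell arrays. HSD3B1 had been at 780 in the 16-cell array, against 23.3 to 44.0 on the morula arrays, while IFNT2 was at 29.9 there, against 15.5 to 87.6. Of 24016 probe sets 40 passed, 29 higher and 11 lower, with 1859 at an unadjusted p under 0.05.

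Of 31 trophectoderm genes 1 passed and 7 rose when adjusted over the list alone, and the list was higher (camera adjusted p = 2.60e-05, and adjusted p = 0.0207 with an estimated correlation). Of 26 cholesterol and fatty acid synthesis genes 1 passed, 7 rose when adjusted over the list alone and 23 had a change above 0, with a median of 0.58 (camera adjusted p = 1.31e-07, and adjusted p = 0.0207 with an estimated correlation). Epithelial junction genes were higher as a list (0 of 34 passed, 1 higher adjusted over the list alone; camera adjusted p = 1.93e-04, and adjusted p = 0.143 with an estimated correlation). Nucleolar and ribosome biogenesis genes (0 of 61 passed, 0 adjusted over the list alone; camera adjusted p = 0.0146, and adjusted p = 0.564 with an estimated correlation) and spliceosome genes (0 of 64 passed, 0 adjusted over the list alone; camera adjusted p = 0.0259, and adjusted p = 0.438 with an estimated correlation) were lower as lists. Neither passed without morula 1 (adjusted p = 0.0674 and 0.0990) or morula 2 (adjusted p = 0.0763 and 0.0885), nor the nucleolar list without blastocyst 1 (adjusted p = 0.118) and the spliceosome list without blastocyst 3 (adjusted p = 0.138) or with the mean of all probe sets per gene (adjusted p = 0.0517). The hypoblast and extracellular matrix list (camera adjusted p = 0.0633) passed without morula 1 (adjusted p = 0.0296), without blastocyst 3 (adjusted p = 0.0235) or without the lowest 33% of probe sets by mean (adjusted p = 0.0417). The cumulus, sperm and blood marker lists did not pass (camera adjusted p = 0.168, 0.761 and 0.845), and HSD3B1 is itself a member of the cumulus and granulosa list.

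UBD, NGEF and HEBP2 rose by 4.84 (SE 0.56), 3.74 (SE 0.48) and 3.72 (SE 0.38), and PLEKHO2 and the epithelial protease PRSS8 by 3.44 (SE 0.43) and 3.43 (SE 0.39). PLEKHO2 at 1228 and HEBP2 at 250 had been above every morula array in the 16-cell array, whereas UBD, NGEF and PRSS8 had not. The falls past the test were ETNPPL at -4.16 (SE 0.46), the transketolase-like gene TKTL1 at -3.99 (SE 0.58), IL2RG at -3.54 (SE 0.51), SRPX at -3.40 (SE 0.51), QPCT at -3.18 (SE 0.41), PPP1R16B at -2.03 (SE 0.32) and CUX1 at -1.75 (SE 0.20). The other probe sets of EPAS1 (1) and CUX1 (2) did not pass. KRT18 was at 9413 ± 2032 in blastocysts against 2906 ± 1844 in morulae (SD, n = 3 each) and did not pass (log2 change 1.85, SE 0.53, adjusted p = 0.337). POU5F1 had a change of -0.24 (SE 0.33, adjusted p = 0.972).

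With only morula and blastocyst arrays in the fit, limma called 0 probe sets (1738 at an unadjusted p under 0.05). The count was 26, 3 and 17 without morula 1, 2 and 3, where the last split into 8 higher and 9 lower, 21 and 71 without blastocyst 2 and 3, 19 and 12 without oocyte 1 and 2, 14 without either 1-cell array, and 95 without the arrays numbered 3.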

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

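All tests of causes in this part were chosen, and the spike-in pattern was defined, after the result was seen. The control probe sets left out of the comparisons carried a signal of their own. The poly(A) spike-in transcripts lys, phe and dap had a mean log2 intensity of 11.62 to 13.18 on 9 arrays and of 2.92 to 6.13 on the other 6, and every replicated stage holds arrays of both kinds. Oocyte 2 stood apart among the 9, with thr at 2632 against 124 to 290 on the other 8. With the class as a block the morula comparison gave 5059 probe sets.

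The arrays numbered 3 of oocyte, morula and blastocyst stood apart from the other arrays of their stage. A labelling batch marked by the spike-in transcripts may be the cause and stays open: the 7 replicate pairs with exactly 1 array of the pattern shared by those 8 differed by 4-fold at 987 probe sets or more, against at most 352 in the other 3 pairs. But 6 of the 7 are the pairs that define the observation, and presence alone goes another way, with 2772 between oocyte 2 and 3, both spiked, and 320 between oocyte 1 and 2. Loss of 5' sequence in the labelled RNA, with array 3 lowest in middle to 3' signal in 5 of 9 comparisons of control genes, and loss of transcripts from low-input RNA also stay open: in 5 of 6 pairs of array 3 with a replicate, 4-fold lower probe sets outnumbered 4-fold higher ones by over 1.5 times. The labels give nothing that sets these arrays apart, and no biological explanation was tested.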

How the results depend on the processing

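The spike-in settings and the removal of the arrays numbered 3 were chosen after the data were seen. The morula count stayed within 1.5 times of 4550 under every setting fixed beforehand (3260 to 4964 with one replicate left out), and rose to 7102 without the arrays numbered 3. The 1-cell count of 65 became 37 with quantile normalization, 35 with median centring, 42 with a pseudocount of 1, 110 without an intensity trend, 8 to 169 with one replicate left out, 0 with only the compared stages, and 419 without the arrays numbered 3. The blastocyst count of 40 became 13 and 66 with pseudocounts of 1 and 64, 3 to 71 with one replicate left out, 0 with only the compared stages, and 95 without the arrays numbered 3. Fits with only the compared stages have 3 or 4 residual degrees of freedom, so few calls follow in part from their construction; the other causes were not tested. Within a spike-in class most groups hold 1 array and 1 or 2 residual degrees of freedom remain, so these fits say nothing about stability: limma called 0 in the 1-cell (4182 without and 895 with spike-in at an unadjusted p under 0.05) and blastocyst comparisons (3404 and 2063) and 6206 without and 0 with spike-in (3795 at an unadjusted p under 0.05) in the morula comparison. The replicate block gave 5513 morula calls, 4443 of them among the 4550, and 35 blastocyst calls, only 26 of them among the 40, and changed no list count in these comparisons. Between oocyte and 1-cell, where the numbers were not treated as pairs, the block gave 38.

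With the correlation estimated per list, the lists past the test fell from 3 to 0 (1-cell), 9 to 1 (morula) and 5 to 2 (blastocyst). Correlation within the lists does not account for all of this loss, since the 2 forms of the test differed even where the estimate was low. The trophectoderm list had an estimate of -0.00552, under the preset 0.01. Its camera adjusted p in the blastocyst comparison still went from 2.60e-05 to 0.0207. Lists numbered 2 to 5 (1-cell), 8 to 9 (morula) and 3 to 7 (blastocyst) with one replicate left out, 8 in the 1-cell comparison within the arrays without spike-in, and 0, 4 and 2 in the 1-cell, morula and blastocyst comparisons within the arrays with spike-in.

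Positions moved by more than the spread of left-out arrays in 4 cases: the 16-cell array to 0.753 (rising) and 0.720 (falling) with quantile normalization and to 0.867 (rising) with the blastocyst as reference, and the 8-cell array to 0.0936 (rising) with a pseudocount of 1. Large steps followed the pseudocount and the size asked for. In the order oocyte to 1-cell, 1-cell to 2-cell, 2-cell to 4-cell, 4-cell to 8-cell, morula to blastocyst and replicates of one stage, a pseudocount of 1 gave 3334.5, 4104.5, 3880, 4361, 3347 and 3648.5, and 64 gave 1028, 1569, 1487, 1917, 1106 and 1273.5. In the same order, with 8-cell to 16-cell and 16-cell to morula put before morula to blastocyst, 2-fold steps numbered 5556, 6288, 5839, 6200, 8371, 7587, 5752 and 6261, and 8-fold steps 567, 1095.5, 1035, 1480, 2715, 1518, 730 and 817.

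Of the named genes past the test, 87 of 96 in the morula comparison kept their call under every setting fixed beforehand, against 0 of 14 in the 1-cell and 0 of 16 in the blastocyst comparison. No named gene past the test changed direction, which follows largely from the selection of large differences and is no sign of stability.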

Other observations

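The tests of scaling, of spike-in class, of somatic genes low elsewhere and of other splits of the arrays were chosen after the result was seen. DNA methyltransferase transcripts followed different courses through the single arrays. DNMT1 stood at 476 in the 2-cell, 331 in the 4-cell, 144 in the 8-cell and 66.1 in the 16-cell array. DNMT3A stood at 1533 in the 2-cell, 423 in the 4-cell, 14.8 in the 8-cell and 588 in the 16-cell array and at 6570 ± 1920 (SD, n = 3) in blastocysts. BMP15 stood at 5556 in the 8-cell and 450 in the 16-cell array, beside 423, 708 and 4779 on the oocyte arrays. Some genes were high in 1 array alone: the nuclear receptor PPARA at 404 and the creatine kinase CKMT2 at 2200.0 in the 8-cell array, against at most 32.4 and 207 in arrays of other stages, and the adrenergic receptor ADRA2A at 608 in the 2-cell array, against at most 13.7. Such genes numbered 18 in the 8-cell and 26 in the 2-cell array, no more than single replicates can give, with 23 in oocyte 3 and 41 in morula 3 against 0 to 3 in the other arrays of those stages. The 16-cell array had 75, more than any replicate array, of which blastocyst 2 had the most at 54. Genes at least 4-fold below every array of the other stages numbered 83 in the 8-cell and 21 in the 16-cell array, beside 85 in oocyte 3 and 70 in morula 3.

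The median of rising probe sets sat at the oocyte level up to the 8-cell array and near the morula at the 16-cell array, although 20.4%, 22.6% and 23.8% of them were past the midpoint in the 2-, 4- and 8-cell arrays, against 14.7% and 16.8% in the 1-cell arrays and 1.65 to 9.35% in the oocyte arrays, on which the probe sets were chosen. Scaling was excluded as the whole cause, since the 16-cell array stayed at 0.753 with quantile normalization. Spike-in class cannot part the 16-cell and 8-cell arrays, which carry the same spike-in pattern. They differed by 0.798 with spiked oocyte and morula arrays as references, oocyte 2 with its other mix included. A labelling batch that the spike-in transcripts do not mark was not tested. RNA of somatic cells in the 16-cell array could add to the rise of genes that such cells share. Called rising trophectoderm and epithelial genes had a median position of 0.449 there (95% bootstrap interval over 19 genes 0.218 to 0.761) and 0.204 in the 8-cell array, which does not decide. The interval does not measure the spread between arrays. ANXA1 and ANXA2, at 1.27 and 0.795 in the 16-cell array, are also in the somatic list used below, so high positions of such genes cannot speak against somatic RNA. Activation of the embryonic genome, which the stages were chosen to cover, stays open beside a wrong label or an unusual single array.

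Some genes of stromal and granulosa cells, picked after their values were seen, were high in the 16-cell array, and a candidate source is somatic cells carried over with the embryos, although the labels' protocol removes cumulus cells by vortexing. Over 44 measured genes of a somatic list written before the test, the median was -0.299 on the log2 scale against the highest of the 8-cell and morula arrays (95% bootstrap interval -0.556 to 0.206), with 12 genes above 1, a median higher than 92.5% of 10000 random lists of matched level. By the bound written beforehand this argued against carry-over; the decision to leave the question open instead was made after the value was seen, because 20 of the 44 genes exceed 500 in an oocyte, morula or blastocyst array, where their own level hides a contribution. Among genes under 200 in the other 14 arrays, 3 of 18 somatic genes (16.7%) and 42 of 2710 others (1.55%) were at least 4-fold above them in the 16-cell array. VIM, among these 3, had been picked after its high value in this array was seen. The excess is thus drawn in part from the observation itself and adds no independent support. VIM at 1959, IGFBP7 at 3273 and IGFBP3 at 3397 go with carry-over and TAGLN at 1, BGN at 18.1 and THY1 at 15.3 do not, and the source stays open.

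The 6 arrays of a comparison part into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. Between oocytes and morulae the real split, fitted to those arrays alone, gave 3589 probe sets and the highest other 0, also among the splits that part all 3 same-numbered pairs. Only 1 split, the real one, reached that count. Every other split puts both stages on each side, so the difference between the stages enters the spread. The counts of 0 follow largely from this and decide nothing. Between morulae and blastocysts the real split gave 0 and the highest other 0, so all 10 gave as many. At an unadjusted p under 0.05 the real split gave 1738 probe sets, and the split that sets morula 1 with blastocyst 1 and 2 against the rest gave 2420, more than the real one; it puts both arrays numbered 3 on the same side and parts 1 pair. Among the splits that part all 3 pairs the real one was highest, against 854, 452 and 518. Whether the numbers pair the arrays is not settled, so this restriction adds no support.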
